A study of Mus musculus with 2 samples.

How the data were processed

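Total RNA was extracted with Trizol from mouse mandibles at E18.5 (embryonic day), and biotin-labelled cRNA was made from 6 µg of it and hybridised to Affymetrix arrays, per the labels' protocols. 1 array was made from a wild-type mandible sample on the BALB/c background and 1 from a mandible sample null for both Myf5 and MyoD on the same background. How many embryos went into each sample is not given in the sources used here. A 1-colour array of this kind measures the brightness of short probes, which are summarised into 1 value per probe set, and a gene can have several probe sets.

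The deposited table holds a log2 value for each of 35557 probe sets on both arrays. That the base of the logarithm is 2 was read from the deposited values, which ran from 1.42 to 13.35 on the wild-type array and from 1.42 to 13.34 on the double-knockout array; a natural or decimal logarithm with this top would exceed what a scanner can record. The submitters' processing notes name MAS5, with no version. MAS5 summarises each array on its own and usually gives linear values, and the step that gave logarithms is not given in the sources used here. Nor is the background correction, the normalization between arrays or the genome build. The medians of the deposited values were 5.48 and 5.45, the ratio of the 2% trimmed means of the linear values was 1.02 (double knockout over wild type), and 1626 probe sets had exactly the same deposited value on both arrays. The 2 arrays were therefore compared as deposited, because the rule fixed in advance allowed this when the trimmed means lay within 5% of each other. If the authors equalised the distributions of the arrays, that rule would be met in any case and would not show that the RNA samples were comparable. A loss of many muscle transcripts would then also raise all others slightly. The median log2 difference over the genes measured was 0.098.

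Gene names came from the platform annotation held by GEO. Of the probe sets, 21789 named 1 gene, 1621 named several and 12147 had no entry. Probe sets of several genes or none entered no gene-level comparison. The 19938 genes were looked up by Entrez identifier in a RefSeq table of the assembly GRCm38.p6, which held 19855 of them and changed 0 symbols; no coordinates are given, since the build behind the array annotation is not stated. The file marks no detection calls. The floor planned was each array's median over non-control probe sets, and since the file marks no controls, it was set at the median of the probe sets with an annotated gene, which was 6.18 on the wild-type array and 6.19 on the double-knockout array. Values under the floor were raised to it. A gene was called measured when it lay above the floor on at least 1 array, and it was represented by its probe set with the highest mean linear signal. A difference with 1 side at the floor is a lower bound and is written as "at least". Differences are double knockout minus wild type on the log2 scale of the floored signal.

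With 1 array per genotype no test between genotypes is possible, and no p-values are given. The only spread that could be measured is that between probe sets of one gene on the same pair of arrays, which leaves out differences between animals and between hybridisations. The log2 differences of the 2 brightest probe sets of a gene differed with an SD of 0.23 over 532 genes with several probe sets above the floor on both arrays. Genes at least 2-fold apart were counted. 27 gene lists with 560 members in all were fixed before the data were examined, as were the percentile of the floor, the fold threshold, the naming rule and most alternatives. 523 members had a probe set of their own, 421 of these were measured, 102 lay below the floor on both arrays, and 37 are not analysed here. The median difference of each list was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. This placing describes these 2 arrays and is not a test of the genotypes; lists outside the central 95% are called below or above the random range.

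The genes named are Myf5 and Myod1, the 10 with the largest fold in each direction among genes above the floor on both arrays whose probe sets all differed in one direction, the 5 brightest in each direction with 1 side at the floor, and up to 4 members of each list with the largest differences, with the 2 brightest members added for the cartilage, hypertrophic cartilage, osteoblast and tendon lists and all members for the sex-linked list. Any gene named outside this rule is said to have been chosen after its values were seen. The number of arrays limits the precision of all values. Alternatives were a median difference set to 0, quantile normalisation, floors at the 25th and 75th percentiles, no floor, the median over the probe sets of a gene, and thresholds of 1.5-fold and 3-fold. Added after seeing the data were a floor at the median of all probe sets and counts without genes of chromosomes X and Y, without the 4 skeletal muscle lists and without the salivary gland list. The code was tested on simulated arrays of 19938 genes made from the wild-type values with noise of SD 0.15 at every signal. The 200 changed genes were drawn only from measured genes that lay above the wild-type floor by a margin. It called 39 of 50 genes lowered by 3 log2 units, 40 of 50 lowered by 1.5, 48 of 50 raised by 1.5 and 50 of 50 raised by 3, with 0 calls among 9979 unchanged genes. A lowered gene that starts close to the floor cannot reach the threshold. Noise this small hardly reaches 2-fold, so the 0 calls check the code and do not estimate false calls between the real arrays. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.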

Results

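The mandible of the mouse fetus was profiled at E18.5, shortly before birth, in a wild-type sample and in a sample lacking both Myf5 and MyoD. These are the transcription factors that commit cells to the skeletal muscle lineage, and fetuses without both form no skeletal muscle. The series asks what skeletal muscle contributes to the development of the lower jaw. Each genotype is represented by 1 array, so every difference compares these 2 arrays and has no replicate check. Across all 35557 probe sets the arrays correlated with a Pearson r of 0.980. Of 10393 genes measured, 9917 were above the floor on the wild-type array and 9944 on the double-knockout array. Where genes had several probe sets above the floor on both arrays, these differed in one direction in 414 of 532 genes (77.8%, 95% Wilson interval 74.1 to 81.1), and in all 7 such genes that were at least 2-fold apart.

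The targeted genes were examined first. Myf5 gave a signal of 6.31 on the wild-type array, just above the floor of 6.18, and was below the floor on the double-knockout array, where its deposited value was 4.95. Its difference was therefore only bounded, at 0.13 or more log2 units lower. Myod1 gave 7.14 on the wild-type array and 6.49 on the double-knockout array, a difference of -0.66 or 1.58-fold lower, with both values above the floor. Both differences run the way the labels state. Where the single probe set of each gene lies relative to the deleted part is not given in the sources used here, so the remaining Myod1 signal neither checks nor contradicts the label.

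Skeletal muscle transcripts made up the lists with the lowest medians. In all, 284 of the 10393 measured genes (2.73%) were at least 2-fold lower in the double knockout and 53 (0.510%) at least 2-fold higher. The 4 skeletal muscle lists together held 108 measured genes, of which 80 were at least 2-fold lower and 0 at least 2-fold higher. Of the 284 lower genes, 156 were at the floor on the double-knockout array, so their folds are lower bounds. Outside the muscle lists 204 genes were at least 2-fold lower, a count made after seeing the data. The lists do not hold every muscle gene, so this is not a count of non-muscle genes. Mstn and Cryab, both made in muscle, are among the 204. The counts of genes lower in the double knockout and genes higher in the double knockout were 531 and 319 at 1.5-fold, 161 and 18 at 3-fold, and 134 and 20 with the floor at the 75th percentile.

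**Figure D1:**
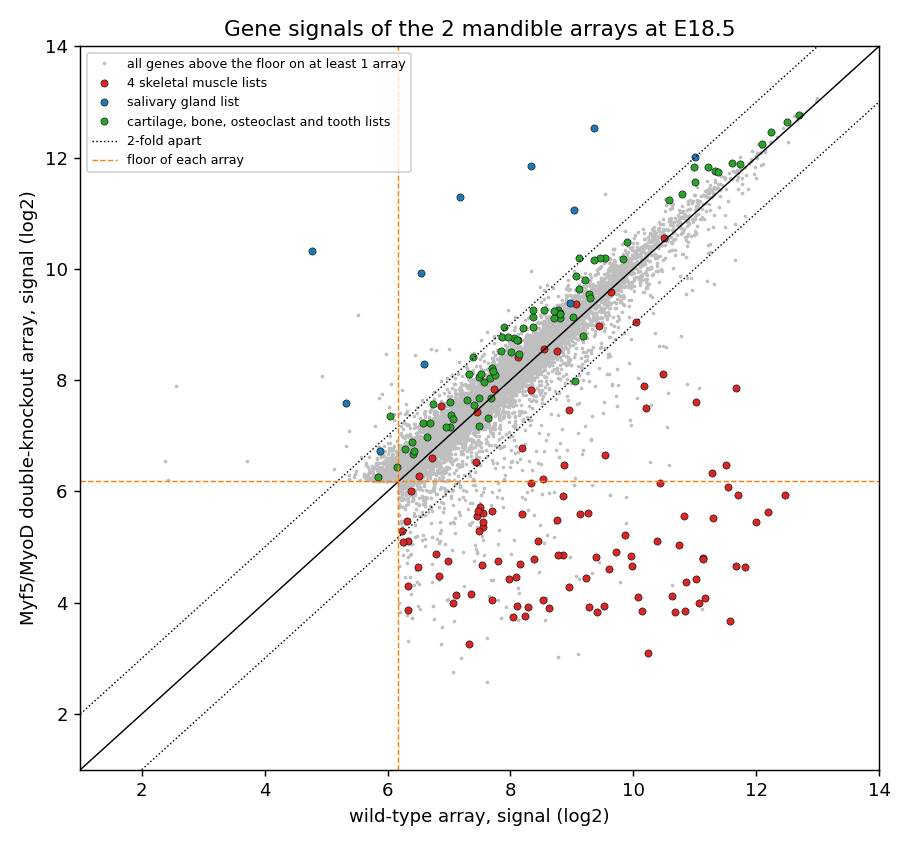
Each point is a gene above the floor on at least 1 array, with its deposited log2 signal before flooring on the wild-type array (x axis) and on the double-knockout array (y axis); dashed orange lines mark the floors at 6.18 and 6.19, dotted lines mark 2-fold apart, and green marks the cartilage, bone, osteoclast and tooth lists. Members of the 4 skeletal muscle lists (red) spread below the diagonal, with 80 of 108 at least 2-fold lower after flooring, while 9 of the 11 measured salivary gland genes (blue) are at least 2-fold higher (8 under either other scaling).

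The sarcomere list had 43 measured members, of which 39 were at least 2-fold lower, 0 were higher and 4 were neither. All 43 were above the floor in the wild type and 3 in the double knockout. The cardiac-type alpha actin Actc1, which fetal skeletal muscle also uses, was at least 77.8-fold lower (12.47 against a deposited 5.94). The skeletal alpha actin Acta1 was at least 64.5-fold lower, the fast troponin T Tnnt3 at least 56.3-fold lower and the perinatal myosin heavy chain Myh8 at least 44.8-fold lower. The median difference was -3.33, lower than the medians of all 10000 random lists. The list of excitation-contraction coupling and muscle energy metabolism had 28 of 30 measured members at least 2-fold lower, with a median of -2.78 (-1.77 with the floor at the 75th percentile), also lower than all random lists. Its members included the sarcoplasmic calcium pump Atp2a1 (at least 49.5-fold lower), the muscle creatine kinase Ckm (at least 46.0-fold), the glycogen phosphorylase Pygm (32.4-fold) and the calcium store protein Casq1 (at least 30.9-fold).

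Among genes above the floor on both arrays, Pygm differed most, followed by the intermediate filament gene Des (31.1-fold lower). The LIM domain gene Pdlim3 was 17.2-fold lower, the muscle enolase Eno3 13.99-fold, the actin regulator Cap2 13.38-fold and the tropomyosin Tpm2 10.6-fold. Mustn1 was 10.5-fold lower, the creatine synthesis gene Gatm 9.32-fold, Fhl1 7.69-fold and the cytochrome oxidase subunit Cox7a1 7.38-fold.

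Of 24 measured members of the list of myogenic regulators, myoblasts and satellite cells, 9 were at least 2-fold lower, 0 higher and 15 neither, with a median of -0.50 that was lower than all random lists. The median was -0.997 with the floor at the 25th percentile and -0.85 at the 75th. Among the 24 were 12 bounds, 7 of them at least 2-fold lower, and others, such as Pax7, began too close to the floor to show a 2-fold difference. Besides Des, these included the myoblast fusion gene Mymk (at least 12.8-fold lower), Tmem182 (at least 9.22-fold) and the myogenic factor Myf6 (at least 5.43-fold). Myog, Pax3 and Pax7 were chosen after their values were seen. Myogenin (Myog) was at least 2.85-fold lower, and the progenitor factor Pax3 was 1.59-fold higher (6.87 against 7.54). The satellite cell factor Pax7 was close to the floor in the wild type (6.25) and below it in the double knockout. In the neuromuscular junction list, 4 of 11 measured members were at least 2-fold lower, all of them bounds: the acetylcholine receptor subunits Chrna1 (at least 3.78-fold), Chrnb1 (at least 3.05-fold) and Chrng (at least 2.55-fold), and acetylcholinesterase, Ache (at least 2.58-fold). The list's median was -0.89, lower than all random lists, but with the floor at the 75th percentile 5 members remained and their median was 0.

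The list of tendon and connective tissue was lower as well, at a smaller scale. Of 24 measured members of the tendon and connective tissue list, 5 were at least 2-fold lower, 0 higher and 19 neither. Tenomodulin (Tnmd), a membrane protein of tendon cells, was 5.64-fold lower. The microfibril gene Mfap5 was 4.48-fold lower, the thrombospondin Thbs4 3.59-fold and keratocan, Kera, 2.98-fold. The brightest members, the proteoglycans Bgn and Dcn, differed by 0.03 and -0.04. Among the 7 higher members were Tnc (0.35) and the tendon factor Mkx (0.10), both named after their values were seen. The tendon factor Scx lay below the floor on both arrays. The median of -0.27 was lower than all random lists, all 24 members were above the floor on both arrays, and 17 of 24 were lower (18 after quantile normalisation and 19 with the median difference set to 0).

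Genes of the jaw skeleton and teeth were slightly higher in the double knockout as groups, although few members were 2-fold apart. In the cartilage list, 15 of 17 measured members were higher (14 under either other scaling), 1 of them at least 2-fold, with a median of 0.33 (percentile 99.98 among random lists). Its members included Ucma, a cartilage matrix protein (at least 2.26-fold higher), Sox9, the chondrocyte master regulator (1.70-fold), the sulfotransferase Chst11 (1.64-fold) and Fgfr3 (1.404-fold). The brightest members were Col2a1 and Col11a1, at 0.49 and 0.12. With the floor at the 25th percentile the cartilage median was 0.18 over 25 members, at percentile 96.1 and so inside the random range, as it was without a floor (0.15). All 10 measured members of the hypertrophic cartilage and Ihh/PTHrP list were higher, none at least 2-fold, with a median of 0.39 (percentile 99.93). They included Panx3 (1.51-fold), the hedgehog target Hhip (1.49-fold), the collagenase Mmp13 (1.47-fold) and the hypertrophic collagen Col10a1 (1.39-fold).

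In the osteoblast and bone matrix list, 18 of 20 measured members were higher (16 with the median difference set to 0), 1 was at least 2-fold lower and 0 at least 2-fold higher, with a median of 0.40 above all random lists. The lower member was the tenascin Tnn (2.11-fold). The proteoglycan Omd was 1.79-fold higher, the Wnt inhibitor Dkk1 1.67-fold and the phosphate-regulating gene Phex 1.57-fold, while the brightest members, Sparc and Col1a1, differed by 0.08 and 0.13. All 14 measured members of the osteoclast list were higher, with a median of 0.70 above all random lists. At least 2-fold higher were 3 of them, but 2 after quantile normalisation and 0 with the median difference set to 0. The 3 were the proton pump subunit Atp6v0d2 (2.12-fold), the carbonic anhydrase Car2 (2.06-fold) and the fusion gene Dcstamp (2.03-fold), with Ocstamp next (1.90-fold). All 17 measured tooth genes were higher and 0 at least 2-fold, with a median of 0.53 above all random lists. They included the dental epithelial factor Sp6 (1.87-fold), the enamel protease Mmp20 (1.77-fold), the dentin gene Dspp (1.75-fold) and Msx1 (1.72-fold).

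Salivary gland transcripts were the only cell type list with most members at least 2-fold higher in the double knockout. Of 11 measured members, 9 were at least 2-fold higher (8 under either other scaling) and 0 lower, with a median of 2.03 above all random lists. The proline-rich secreted protein Prol1 was at least 17.7-fold higher, with deposited values of 4.77 and 10.32. Pip was 17.4-fold higher (7.17 against 11.30), the submandibular gland protein Smgc 11.4-fold (8.34 against 11.86), the peroxidase Lpo 10.5-fold and the secreted protein Bpifa2 9.06-fold. The salivary mucin Muc19 was 4.08-fold higher, with its 2 probe sets in one direction, and the water channel Aqp5 3.25-fold. Other genes with the largest folds on both-sided values were Dcpp2 (4.005-fold), whose probes may be shared with close paralogs, the calcium pump Atp2a3 (3.57-fold), the protease inhibitor A2ml1 (3.50-fold) and the transporter Slc5a8 (3.40-fold). With the wild type at the floor, the secreted carbonic anhydrase Car6 was at least 7.94-fold higher, Elapor1 at least 4.87-fold, BC018473 at least 3.73-fold and the chemokine Ccl28 at least 3.35-fold. Markers of both sexes were unevenly spread over the arrays beside this difference. Eif2s3y was above the floor in the double knockout alone (2.38 against 6.55), as was Uty (2.43 against 6.20, where the floor was 6.19), Kdm5d was below it on both (3.42 against 5.27), and Xist was above it on both (10.87 against 10.22). Without genes on chromosomes X and Y, an alternative chosen after seeing the data, there were 267 genes lower in the double knockout and 53 genes higher in the double knockout.

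**Figure D2:**
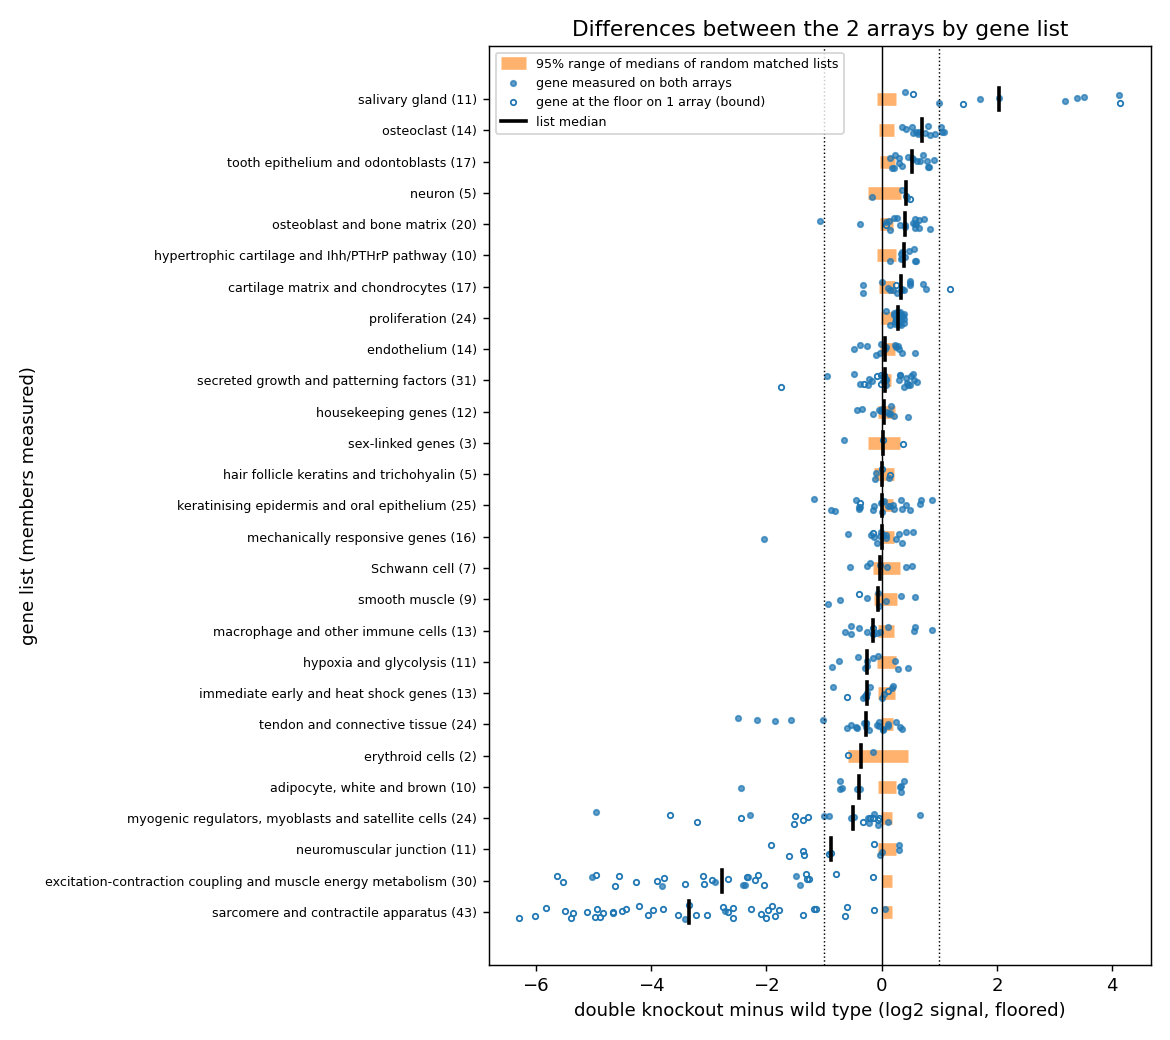
Rows are the gene lists with the number of measured members, ordered by median, and the x axis is the log2 difference, double knockout minus wild type, with filled points for genes above the floor on both arrays, open points for bounds with 1 array at the floor, black bars for list medians, orange bands for the central 95% of medians of random lists matched on signal, and dotted lines at 2-fold. The sarcomere list lies lowest (median -3.33) and the salivary gland list highest (2.03).

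Other cell types of the jaw were near the median of all genes or mixed. The endothelial list (14 members, median 0.07), the Schwann cell list (7, -0.021), smooth muscle (9, -0.07), keratinising epithelium (25, 0.01) and hair keratins (5, 0.010) lay inside the random range. So did the erythroid list (median -0.36), which rested on 2 members, Slc4a1 and Alas2. The endothelial, epithelial and hair medians were negative with the median difference of all genes set to 0. Without a floor, the epithelial, Schwann cell, erythroid and smooth muscle lists were below the random range. With the floor at the 25th percentile the Schwann cell and smooth muscle lists were below it too (percentiles 1.63 and 0.09). The Schwann cell list was also below it with the floor at the median of all probe sets. Within the epithelial list, the cornified envelope genes Sprr1a and Lor were 2.26-fold and 1.83-fold lower and the oral keratin Krt4 1.76-fold lower, while the epithelial adhesion gene Epcam was 1.82-fold higher. The smooth muscle actins Acta2 and Actg2 were 1.91-fold and 1.65-fold lower and the myosin kinase Mylk 1.498-fold higher. The neuron list was above the random range on 5 members (median 0.42), among them Tubb3 (at least 1.41-fold higher) and Stmn2 (1.36-fold), but with the floor at the 75th percentile 1 member remained and the list lay inside the range, and without a floor the median was 0.24. In the immune list (13 members, median -0.15, percentile 0.14), C1qc was 1.55-fold lower and Cd68, which osteoclasts also express, 1.82-fold higher. The list's median was -0.25 with the median difference set to 0. With the floor at the 75th percentile 5 members remained, and their median of 0.57 lay above the random range. In the adipocyte list (10 members, median -0.40, percentile 0.02), the 1 member at least 2-fold lower was Gpd1 (5.41-fold), a glycerol phosphate dehydrogenase that muscle also makes. Car3, Fabp4 and Lpl, which muscle tissue also expresses, were 1.66-fold, 1.65-fold and 1.61-fold lower. The list's median was -0.64 with the floor at the 75th percentile. It was 0.20, above the random range, with the floor at the 25th percentile and without a floor.

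Lists of cell state differed by less than 2-fold except for single members. All 24 measured proliferation genes were higher (23 with the median difference set to 0), none at least 2-fold, with a median of 0.28 (percentile 99.97; 0.19 with that setting) and the largest differences in Ube2c and Top2a (both 1.31-fold). The hypoxia and glycolysis list was lower (median -0.25, percentile 0.125; -0.14 with the floor at the 25th percentile and -0.15 at the 75th), led by Aldoa (1.81-fold), the main aldolase of muscle, and Pdk1 (1.66-fold), whereas the glucose transporter Slc2a1 was 1.37-fold higher. The immediate early and heat shock list was lower (median -0.25, percentile 0.02), with Dusp1 1.79-fold and Atf3 at least 1.52-fold lower, but its median was -0.11 with the floor at the 25th percentile and inside the random range with the floor at the 75th (-0.10). Of 31 secreted growth and patterning factors, 1 was at least 2-fold lower. This was myostatin, Mstn, the muscle-made inhibitor of muscle growth (at least 3.34-fold). Fgf18, a growth factor of skeletal development, was 1.94-fold lower, Fgf10 1.54-fold higher and Bmp7 1.48-fold higher, and the list's median of 0.06 lay inside the random range (-0.034 with the median difference set to 0). Of 16 mechanically responsive genes, 1 was at least 2-fold lower, the small heat shock protein Cryab (4.13-fold), which is abundant in muscle. Tead1 was 1.49-fold lower, the mechanosensitive channel Piezo2 1.47-fold higher and Ccn2 1.34-fold higher. The 16 had a median of 0.00 on the log2 scale. The 12 housekeeping genes had a median of 0.05 (-0.050 with the median difference set to 0), with Gusb the highest (1.37-fold higher) and Sdha the lowest (1.35-fold lower).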

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

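Signals outside the gene-level comparison were looked for in the probe sets that name several genes or none, as differences from the wild-type array. The 2 tests of the salivary gland pattern below were chosen after its values were seen. Among 757 probe sets naming several genes and lying above the floor, 1 was at least 2-fold higher in the double knockout and 6 at least 2-fold lower. Among 2997 probe sets without an annotated gene, 12 were at least 2-fold higher and 23 at least 2-fold lower.

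A dilution effect, in which the loss of muscle RNA raises every other transcript, would raise the salivary gland genes by the same amount as other non-muscle lists, but their median exceeded the highest of 15 other non-muscle lists (0.70) by 1.33, against an SD of 0.084 among random lists. A larger share of the same gland tissue in the double-knockout sample would in the simplest case raise gland transcripts by one amount. The 8 members above the floor on both arrays differed by 0.41 to 4.12 with an SD of 1.33. The 8 muscle energy genes above the floor on both arrays had an SD of 1.20. These are the 8 of 30 measured members that stayed above the floor in the double knockout, so they do not show a clean loss of one tissue. A spread of this size therefore does not decide, and a larger gland share stays open. So do a different mix of glands or cell types in the dissected tissue, the sex of the embryos and an effect of the genotype, which were not tested and which 1 array per genotype does not separate.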

How the results depend on the processing

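No paired analysis was possible because each genotype has 1 array. Scaling on spike-in controls was not run, because the file marks no control probe sets, and neither was a restriction to identifiers without suffixes, because all are plain numbers. Of 27 lists, 15 kept their side of the random range under all 6 alternatives that can change it (setting the median to 0 moves random lists alike), and the hair keratin list did so under the 5 of these that left it members (none were above the floor at the 75th percentile). None changed side with quantile normalisation or with the median over probe sets. Both settings could change little here. The deposited medians were already close (5.48 and 5.45), and 21789 probe sets stood for 19938 genes. Signal near background limits the list values, since the floor decides which genes count and how far a bound reaches. The cause was not tested further. The count of genes lower in the double knockout was 284 and that of genes higher in the double knockout 53. With the floor at the 75th percentile they were 134 and 20, and without a floor 431 genes were lower. At 1.5-fold they were 531 and 319, and at 3-fold 161 and 18. Under the scaling alternatives and the counts added later they stayed within 1.5 times these (267 lower without chromosomes X and Y, 204 lower without the muscle lists, 44 higher without the salivary list). Probe sets of one gene had one direction in 73.0% of genes with the floor at the 25th percentile and 85.7% at the 75th.

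Setting the median to 0 lowered every list by 0.098, giving sarcomere -3.43, contraction and energy -2.87, myogenic -0.60, neuromuscular -0.98, cartilage 0.24, hypertrophic cartilage 0.29, osteoblast 0.30, osteoclast 0.60, tendon -0.37, tooth 0.44, epithelium -0.091, hair -0.088, salivary 1.93, endothelium -0.032, immune -0.25, adipocyte -0.50, growth factors -0.034, mechanical -0.098, immediate early -0.35, proliferation 0.19, hypoxia -0.35 and housekeeping -0.050. The floor at the 25th percentile gave sarcomere -4.79, contraction and energy -3.54, myogenic -0.997, cartilage 0.18, salivary 2.26, immune -0.22, smooth muscle -0.26, immediate early -0.11, hypoxia -0.14 and sex-linked 1.503, and the adipocyte list turned to 0.20. The floor at the 75th percentile gave sarcomere -2.44, contraction and energy -1.77, myogenic -0.85, neuromuscular 0, cartilage 0.49, osteoblast 0.34, salivary 2.19, Schwann -0.26, adipocyte -0.64, smooth muscle 0.040, growth factors 0.13, immediate early -0.10, hypoxia -0.15 and sex-linked -0.65, and the immune list turned to 0.57. Without a floor the values were sarcomere -4.79, contraction and energy -3.54, myogenic -0.97, cartilage 0.15, hair 0.12, neuron 0.24, smooth muscle -0.26, immediate early -0.11, hypoxia -0.15 and sex-linked 2.81, and the adipocyte list again turned to 0.20. With the floor at the median of all probe sets they were sarcomere -3.87, contraction and energy -2.94, myogenic -0.91, hair 0.11, Schwann -0.21, immune -0.22, adipocyte -0.24, immediate early -0.11, hypoxia -0.15 and sex-linked 0.72. The median over probe sets gave contraction and energy -2.42 and salivary 2.21. Of the 132 named genes with values, none that was at least 2-fold apart changed sign under the alternatives that gave it a value. These settings could hardly turn such a sign, since the shift was 0.098 and a floor mainly shortens or lengthens a difference. The kept signs are therefore weak support. With the floor at the 75th percentile 28 named genes had no value, and 42 moved by at least the SD between probe sets of one gene (0.23). With the floor at the 25th percentile 23 moved by that much, as did 23 without a floor and 23 with the floor at the median of all probe sets. The sizes of these differences therefore depend on the floor. The floor at the median of all probe sets was chosen after seeing the data, as were the counts without chromosomes X and Y and without the muscle or salivary lists.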

Other observations

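The imprinted cluster on chromosome 12 between Dlk1 and Dio3, which holds the noncoding RNAs Meg3 and Rian and many microRNA genes, was lower in the double knockout. It was chosen after its values were seen. All 26 measured genes of the cluster were lower and 16 at least 2-fold, against 7 of 339 other measured genes of that chromosome, with a median difference of -1.29 in the cluster. Meg3 was 2.69-fold lower (11.20 against 9.78), the retrotransposon-derived gene Rtl1 at least 2.40-fold, Rian at least 2.20-fold, and Dlk1 1.29-fold. The Rian bound comes from a dim probe set (7.32 in the wild type). A brighter probe set that names both Rian and AF357355, and so entered no gene-level comparison, differed by -2.27 (9.08 against 6.81). Of 21 measured microRNA genes 12 were at least 2-fold lower, among them Mir377 (at least 4.91-fold) and Mir134 (4.13-fold). Many of these genes lie within one host transcript, so their values are not independent.

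Of 6 measured Hspb genes, which encode small heat shock proteins and were also chosen after their values were seen, 5 were at least 2-fold lower, among them Hspb7 (at least 10.8-fold), Hspb1 (3.92-fold) and Hspb6 (3.31-fold). Near the targeted genes, where genes are named after their values were seen, 100 measured neighbours of Myf5 on chromosome 10 (50 on each side) included 3 at least 2-fold lower (Mybpc1, Kera and Myf6) and 1 higher (Slc5a8). The 100 neighbours of Myod1 on chromosome 7 included 6 lower (Mybpc2, Rras, Hrc, Gys1, Mamstr and Csrp3) and 0 higher.

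The 4 tests of the next patterns were chosen after the values were seen. The 78 measured members of the bone, cartilage, osteoclast and tooth lists had a median of 0.48 and the 80 members of 8 other lists (epithelium, hair, neuron, Schwann cell, endothelium, erythroid, immune and smooth muscle) a median of -0.015. Dilution by the loss of muscle RNA would raise both alike if no cells of either set are lost with muscle. The medians lay 0.49 apart, where the central 95% of random lists ended at 0.084. With the tendon, adipocyte and salivary lists added they lay 0.50 apart, against 0.073. This argues against an equal rise of all non-muscle lists. Vessel, nerve, immune, tendon or fat cells within muscle may be lost with it, so the gap does not decide on dilution of the skeletal lists. A larger share of bone, cartilage and tooth tissue in the double-knockout sample would raise the brightest genes with the rest. The median of the brightest 19 was 0.55, where random lists ended at 0.20, and that of the rest was 0.47. The 6 brightest (Sparc, Col1a1, Ibsp, Col1a2, Amelx and Ambn) differed by only 0.08 to 0.29. Members almost as bright (Enam, Ctsk, Mmp13, Acp5 and Mmp9) differed by 0.36 to 0.84. Both groups were named after their values were seen, and neither decides. A larger share of these tissues therefore stays open, as does an untested hypothesis that regulation within them differs by genotype.

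The Y-linked signal bears on what the samples contain. A single female wild-type embryo against a single male double-knockout embryo would leave Xist at background in the double knockout, but it lay 4.03 log2 units above the floor, against a spread of 0.23. RNA of embryos of both sexes in the double-knockout sample would show Xist with Y-linked genes; 2 of 3 Y-linked genes were above the floor there, Uty barely (6.20 against 6.19), and 0 on the wild-type array, which is consistent with a pool of embryos. The sources used here do not state the number or sex of the embryos. Y-linked signal differed between the arrays along with genotype, so sex cannot be told apart from genotype in any difference given here. Leaving out genes on chromosomes X and Y does not remove effects of sex on other genes.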
